A study of Homo sapiens with 22 samples.

How the data were processed

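Total RNA of 22 samples was depleted of ribosomal RNA, amplified with random primers into Cy3-labelled cRNA and hybridised to one-colour arrays, 1 array per sample, per the labels' protocols. Signals were extracted with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers, on a probe design annotated to hg19. The intensity values used (the processed signal of each spot) were background-subtracted and spatially detrended within the array by that software, per the file headers, and were not normalised between arrays. The raw median intensity of each spot and of its local background, also deposited by the authors, was used only for an alternative background correction. The authors deposited a table of log2 values of the same arrays as well, with 60208 of the 60639 probes. How it was scaled is not given in the sources used here. Each of its 22 columns correlated best with the log2 processed signal of its own array (r of 0.989 to 0.999), column medians lay between 5.02 and 5.03 and differences between arrays had a slope of 1.07 against those of the processed signal, so the direction is settled, and the normalisation behind it stays unknown. That table served as an alternative. The other flags read from the files mark spots that are not uniform, population outliers, saturated or well above background.

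Control spots and spots marked as outliers were left out, and spots of one probe were averaged on the log2 scale. Signals were taken as log2 intensity minus the 75th percentile of the array. A probe was tested if it was well above background on at least 3 arrays of at least 1 group of the fit. Of several probes with one gene name, the one with the highest mean signal stood for the gene, chosen anew in each fit. In fits on part of the normal and tumour arrays, or on other signals of them, this exchanged the probe of some HOX genes, among them HOXB13 and HOXD11. Names came from the probe names of the files. Of 65 RefSeq accessions in them 63 were matched to a gene symbol through the RefSeq gene table, which gave 93 exon and 53 intron probes of HOX regions and 20 reference mRNAs, besides 213 nc-HOX probes, 962 probes of ultraconserved regions (uc, with the strand as + or -) and 25 other named probes. The 59273 further probes carry only the manufacturer's identifier, and no table pairing those with genes was used here. Genomic positions are not given for the same reason.

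Groups were taken from the labels: control siRNA and MYC siRNA in HCT116 and in RKO (3 arrays each), normal samples (4 cell lines and 1 tissue) and tumour samples (4 cell lines and 1 tissue). Arrays scanned together were taken as one slide, which gave 3 slides. Features were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with 1 fit of 4 group means for the 12 siRNA arrays and another for the 10 normal and tumour arrays, and with Benjamini-Hochberg adjustment over all features of a contrast at an adjusted p of 0.05. The knockdown fit tested 41423 features and had 8 residual degrees of freedom (prior 2.33), the tumour fit 39911 features and 8 (prior 2.66). The contrasts were knockdown minus control in each line, the difference of these contrasts (RKO minus HCT116) and tumour minus normal. The number of features called in both lines was set beside the number expected from independent lists. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for reading files and drawing plots.

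Tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule took, per contrast, among named features past the threshold whose groups did not overlap, the 8 largest rises and falls, the 4 largest rises and falls of non-coding features, up to 4 members of each list past the threshold, the 5 smallest adjusted p in each direction for the difference between lines, the 5 largest mean rises and falls shared by both lines, and the 5 features with the smallest sum of adjusted p ranks in the overlap with the tumour contrast. It placed MYC first, for which no named probe was found. HOXB2 and HOXB4 to HOXB8, EIF3D, ODC1 and HOTAIRM1 in HCT116, HOXB4, DYNLL1, H3-3A and ODC1 in RKO, COX4I1 in both lines, HOXB9, HOXB8, HOXC10, HOXB13, uc.452- and nc-HOXC6-240 in the tumour contrast and the unnamed identifiers were chosen after their values were seen, as were all statements on single exon probes. Bounds on features that some arrays of the dimmer group measured were also added after the values were seen, as were the list tests with unchanged probes.

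The 25 lists covered the MYC network, ribosome biogenesis, ribosomal proteins, nucleotide and polyamine synthesis, translation factors, glycolysis, oxidative phosphorylation, DNA replication, mitosis, growth arrest genes repressed by MYC, p53 targets, interferon response, unfolded protein and amino acid stress, cholesterol synthesis, annotated long non-coding RNAs, Wnt targets, HOX genes, cancer-testis genes and markers of epithelial, fibroblast, smooth muscle, immune, endothelial, mature colonocyte and red blood cells. Only 7 had a tested member (ribosomal proteins, nucleotide and polyamine synthesis, translation factors, glycolysis, oxidative phosphorylation, long non-coding RNAs and HOX genes), so the cell types in the samples were not analysed here. The 3 lists with at least 2 tested members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a contrast. Probe families (HOX clusters, introns, nc-HOX transcripts, ultraconserved regions, reference mRNAs) were added as lists after the files were seen.

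The precision of each value is limited by the number of arrays. The fits were tested on simulated scaled signals with the means and spreads of the real features, with 100 features changed by each of 2 sizes. With a true change of 1 on the log2 scale, 31% of 100 changed features were recovered in the HCT116 contrast, 37% in RKO and 0% in the tumour contrast. With a true change of 2 it was 83%, 74% and 14%. None had the wrong sign, and 5, 6 and 1 unchanged features were called. The simulated features varied independently of each other and held no slide shift. These shares and counts therefore do not cover slide effects, the scaling or the filter on dim probes in the real arrays. The alternatives tried were quantile normalisation, a shift by the median, normexp background correction (offset 50), the authors' table, other filters on dim probes, each probe as its own feature, a trended robust variance model, the slide as a block, the replicate number as a block, a 2-fold minimum, array weights, only the arrays of a line, only cell lines, only the arrays of single slides, the overlap without untreated HCT116 and RKO, and leaving out each array in turn.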

Results

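RNA from 22 samples was hybridised to one-colour Agilent arrays that carry probes for protein-coding transcripts, long non-coding RNAs, the exons, introns and non-coding transcripts of the HOX clusters, and ultraconserved regions. The 12 siRNA arrays came from HCT116 and RKO, both human colorectal carcinoma lines, each treated with control siRNA (3 arrays per line) or with siRNA against MYC, a transcription factor that promotes growth and proliferation (3 arrays per line). The other 10 arrays compared normal with tumour samples of the colon. The normal group held the lines CCD-18Co, CCD-33Co, CCD-112CoN and CCD-841CoN and 1 normal colon tissue, and the tumour group held untreated HCT116, RKO, SW620 and HT29 and 1 tumour colon tissue. The comparisons ask which coding and non-coding transcripts change when MYC is reduced and which differ between normal and tumour samples of the colon.

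Each array held 60639 probes, of which 1366 could be given the name of a gene, a HOX-cluster transcript or an ultraconserved region and 59273 had only the manufacturer's identifier. The share of probes well above background ran from 67.3% to 75.2% on slide 1, from 51.1% to 62.1% on slide 2 and from 59.9% to 68.5% on slide 3. Slide 1 carried all 6 HCT116 siRNA arrays and RKO control replicates 1 and 2. Slide 2 carried RKO control replicate 3, the 3 RKO knockdown arrays and the 4 normal cell lines. Slide 3 carried the normal tissue and the 5 tumour samples. Arrays of one siRNA group correlated across probes with r of 0.957 to 0.988, normal samples with 0.864 to 0.967 and tumour samples with 0.854 to 0.946, and no replicate arrays held identical values beyond 0.00165% of probes. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of each value.

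**Figure D1:**
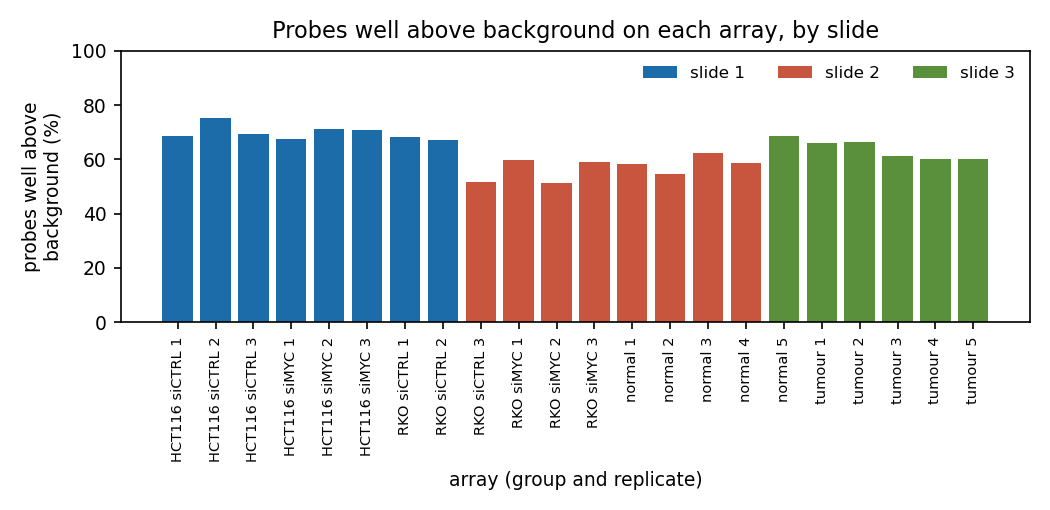
Percentage of the 60639 probes that were well above background on each of the 22 arrays (bars, 1 per array), coloured by slide. The 8 arrays of slide 2, which include RKO control replicate 3 and all RKO knockdown arrays, lie between 51.1% and 62.1%, below the 67.3% to 75.2% of slide 1.

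None of the named probes was named for MYC, so the level of the knocked-down gene was not analysed here and the groups rest on the labels alone. In HCT116, HOXB3, a homeobox transcription factor of the HOXB cluster, rose 1.90-fold after MYC knockdown (log2 fold change 0.92 ± 0.14 (SE), 3 arrays per group, adjusted p = 0.00344), from a mean normalised log2 signal of 4.03 ± 0.25 (SD, n = 3) to 4.95 ± 0.05. HOXC5 and HOXC13, homeobox genes of the HOXC cluster, fell to 0.535 and 0.554 of their control level (log2 fold changes -0.90 ± 0.16 and -0.85 ± 0.14, adjusted p = 0.00829 and 0.00476). HOXA4 fell to a log2 fold change of -0.61 ± 0.15 (adjusted p = 0.0345), and PRMT1, the main arginine methyltransferase for histones and RNA-binding proteins, to -0.62 ± 0.16 (adjusted p = 0.0393). The exon 1 probes of HOXC5, HOXC13 and HOXA4 had -0.15, -0.23 and -0.29 (adjusted p = 0.869, 0.855 and 0.801). For each of the chosen probes all knockdown arrays lay on one side of all control arrays. HOXB3, HOXC5 and HOXC13 stayed past the threshold without any 1 of the 6 HCT116 arrays (highest adjusted p 0.0203, 0.0413 and 0.0275). PRMT1 and HOXA4 each lost the call in 5 of the 6 such fits, all but the one without control replicate 1, with adjusted p up to 0.13 and 0.121.

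The non-coding features of HCT116 moved in both directions. The ultraconserved region uc.456+ rose 2.45-fold (log2 1.29 ± 0.21, adjusted p = 0.00502), and nc-HOXB2-164, a non-coding transcript of the HOXB cluster, rose by 0.91 ± 0.22 on the log2 scale (adjusted p = 0.0337). Where a probe was not well above background on arrays of its dimmer group, its signal there is only an upper limit. Its change is then given as a bound, computed against the higher of the probe's own signal and the lowest signal well above background on each array. The brighter group is taken at its own mean, so a fold is marked as no bound where that group held arrays not well above background. On that basis uc.234+ was at least 4.86-fold lower (adjusted p = 0.00543), with 1 of 3 knockdown arrays and 3 of 3 control arrays well above background, uc.392+ was at least 1.73-fold lower (adjusted p = 0.0147) and uc.411+ at least 1.5-fold lower (adjusted p = 0.0103), the latter 2 measured on all 3 control arrays and on no knockdown array. The region uc.341+ fell by 0.95 on the log2 scale (adjusted p = 0.0419). Of the 345 ultraconserved regions tested 1 rose and 6 fell, and of 156 nc-HOX transcripts 1 rose and 1 fell. Leaving out single arrays ended the calls of nc-HOXB2-164 (4 of 6 fits), uc.392+ (5 of 6) and uc.341+ (5 of 6), with adjusted p up to 0.119, 0.0601 and 0.143.

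Of the 25 gene lists fixed before the data were examined, 18 had no tested member on these arrays, among them the MYC network, ribosome biogenesis, cell cycle and cell type marker lists. The HOX list had 36 members tested in HCT116, of which 1 rose, 3 fell and 32 did not pass the threshold. With the slide as a block, which leaves the HCT116 fold changes as they are, 4 rose and 5 fell. Adjusted over the list alone, 5 rose and 3 fell, and camera gave no shift of the list as a whole (median log2 fold change 0.01, adjusted p = 0.53). None of 3 ribosomal protein genes (RPL10, RPLP1, RPS18) and neither of 2 glycolysis genes (PGK1, GAPDH) passed over all features or adjusted over the list alone, and camera gave adjusted p = 0.53 for both lists. ODC1, the rate-limiting enzyme of polyamine synthesis, had a log2 fold change of -0.48 ± 0.16 (adjusted p = 0.114), EIF3D, a translation initiation factor subunit, -0.48 ± 0.13 (adjusted p = 0.0543), HOTAIRM1, a long non-coding RNA of the HOXA cluster, -0.36 ± 0.13 (adjusted p = 0.172) and COX4I1, a subunit of cytochrome c oxidase, -0.23 ± 0.10 (adjusted p = 0.224). Each was the only tested member of its list, so that adjusted over the list alone its p is the unadjusted one. That was under 0.05 for all 4, and none passed over all features. With the slide as a block, at unchanged fold changes, only EIF3D of these passed over all features. After quantile normalisation ODC1, EIF3D and HOTAIRM1 had -0.28, -0.28 and -0.26 (adjusted p = 0.321, 0.102 and 0.218). Without control replicate 1, ODC1 and EIF3D passed over all features (adjusted p = 0.0107 and 0.0491). Across all 41423 tested features 1140 rose and 1755 fell, of which 256 and 420 changed at least 2-fold. The excess of falls depended on the scaling: quantile normalisation gave 1825 rises and 1764 falls, and the values deposited by the authors gave 1920 and 1836. All 6 arrays shared slide 1. The 2895 calls became 1831 and 1705 without control replicates 3 and 2, and 1389, 1475 and 1438 without knockdown replicates 1, 2 and 3. With the slide as a block they became 4970 (1978 rises and 2992 falls), with the 2895 among them. Since the 6 arrays shared 1 slide, the block leaves the HCT116 fold changes as they are. It changes only the spread, which is shared with the RKO arrays, so the added calls are no correction for the slide.

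In RKO, 6 of 10 HOXB genes rose after MYC knockdown and none fell. HOXB5 rose 2.98-fold (log2 1.57 ± 0.21, adjusted p = 0.00187), from 2.60 ± 0.32 (SD, n = 3) to 4.17 ± 0.13. HOXB6 rose 2.89-fold (log2 1.53 ± 0.21, adjusted p = 0.0021), HOXB2 2.48-fold (log2 1.31 ± 0.17, adjusted p = 0.00174), HOXB8 2.31-fold (adjusted p = 0.0115), HOXB7 1.87-fold (adjusted p = 0.00725) and HOXB3 1.81-fold (log2 0.85 ± 0.14, adjusted p = 0.00405). In the HOXA cluster, HOXA13 rose by 1.16 and HOXA10 by 0.87 on the log2 scale (adjusted p = 0.00443 and 0.0081), while their exon 1 probes had 0.25 and -0.31 (adjusted p = 0.224 and 0.191). With the slide as a block, which sets the knockdown arrays against the control array of their own slide, HOXB5, HOXB6, HOXB2, HOXB3 and HOXA13 kept log2 fold changes of 1.21, 1.41, 0.93, 0.73 and 1.52 (adjusted p = 0.0167, 0.0172, 0.0101, 0.03 and 0.00309). The calls of HOXB8, HOXB7 and HOXA10 ended with the block, where their log2 fold changes were 1.04 ± 0.36, 0.65 ± 0.21 and 0.74 ± 0.23 against 1.21 ± 0.25, 0.90 ± 0.17 and 0.87 ± 0.17 without it (adjusted p = 0.0917, 0.072 and 0.0635). All 8 HOXA and HOXB genes named here stayed past the threshold without any 1 of the 6 RKO arrays. Without control replicate 3, though, the slide and the knockdown cannot be told apart. The spread in these fits was shared with the HCT116 arrays, and the genes were not read from a fit of the RKO arrays alone.

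**Figure D2:**
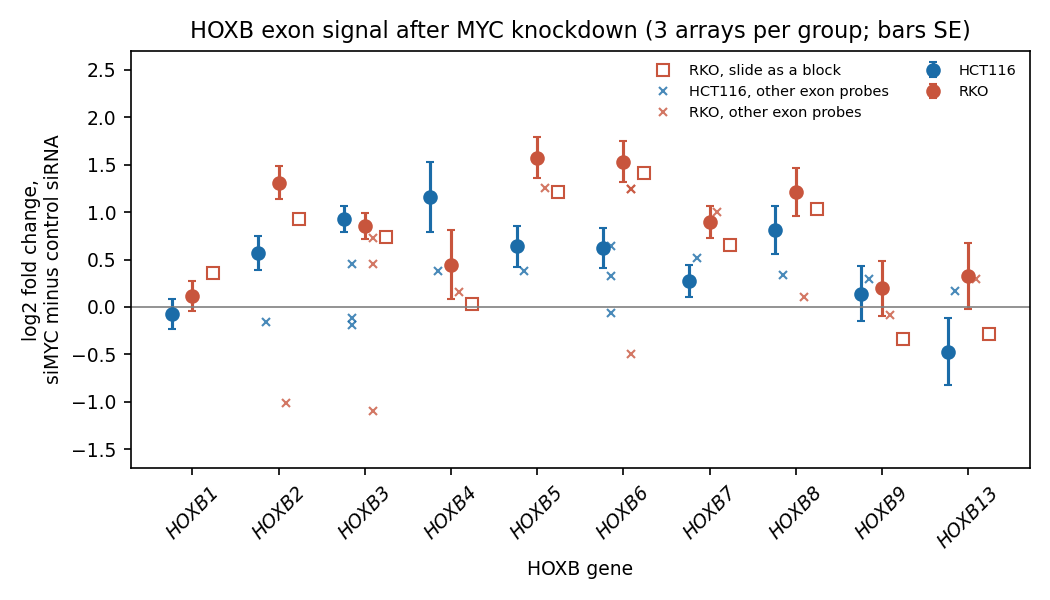
Log2 fold change of HOXB exon signal after MYC knockdown in HCT116 and RKO (y axis) for the 10 tested HOXB genes (x axis). Filled circles with SE bars are the brightest probe of each gene, open squares are the RKO value with the slide as a block, and crosses are the other exon probes of the same genes. All 10 brightest probes lie above 0 in RKO and 8 in HCT116, while single other exons of HOXB2 and HOXB3 lie near -1 in RKO.

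Among other coding genes of RKO, PGK1, a glycolytic kinase, rose 1.83-fold (log2 0.88, adjusted p = 0.00736), and of the other reference mRNAs of the array DYNLL1, a dynein light chain, rose by 0.72 (adjusted p = 0.00535) and H3-3A, which encodes histone H3.3, by 0.51 (adjusted p = 0.032). The block left DYNLL1 past the threshold (adjusted p = 0.0371) and ended the calls of PGK1 (0.59 ± 0.19 against 0.88 ± 0.16, adjusted p = 0.0744) and H3-3A (0.25 ± 0.15 against 0.51 ± 0.14, adjusted p = 0.318). HOXC4 fell by 0.74 ± 0.17 (adjusted p = 0.016), and with the block its log2 fold change was -0.42 ± 0.19 (adjusted p = 0.174), while HOXD10 was at least 1.05-fold lower (adjusted p = 0.00825; with the block 0.003), measured on 3 control arrays and on no knockdown array. EIF3D fell by 0.45 (adjusted p = 0.0391; with the block 0.0143), ODC1 had a log2 fold change of 0.18 (adjusted p = 0.47), and HOTAIRM1 rose by 0.47 ± 0.13 (adjusted p = 0.0384), with 0.30 ± 0.17 under the block (adjusted p = 0.277). Calls of H3-3A, EIF3D and HOTAIRM1 were lost in 5 of the 6 fits without 1 RKO array, all but the one without control replicate 3 (adjusted p up to 0.119, 0.117 and 0.129), and HOXC4 in 4 of 6 (up to 0.0649). In the fit without control replicate 3 the slide and the knockdown cannot be told apart.

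Among non-coding features of RKO, uc.416- rose 2.53-fold (log2 1.34, adjusted p = 0.000694; with the block 0.00542) and nc-HOXB9-199 3.51-fold (adjusted p = 0.0107), a rise that was 0.65 on the log2 scale with the block (adjusted p = 0.0099). The region uc.184- was at least 2.79-fold higher (adjusted p = 0.0114; with the block 0.0326), measured on 3 knockdown arrays and no control array. The transcript LUST, measured on 2 control arrays only, fell (adjusted p = 0.00447, with the block 0.0475), with a fold of 1.27 that is no bound. The call of uc.97+, which rose by 1.31 ± 0.37 and had 0.18 ± 0.18 with the block, ended with the block (adjusted p = 0.558). So did those of uc.41+ and uc.350+ (adjusted p = 0.0597 and 0.592). These 2 were lower on 2 measured control arrays, with folds of 1.15 and 1.11 that are no bounds. Both uc.458+ and uc.234+ fell (adjusted p = 0.00804 and 0.0245). They were measured on 2 control arrays and gave no bound on the fold, and the block ended both calls (adjusted p = 0.0725 and 0.166). The fitted values of uc.41+, uc.350+, uc.458+ and uc.234+, which are no bounds, went from -2.44 ± 0.48, -1.82 ± 0.53, -1.995 ± 0.383 and -1.47 ± 0.37 to -1.09 ± 0.33, -0.39 ± 0.42, -0.99 ± 0.32 and -1.24 ± 0.54. Without single RKO arrays the calls of uc.97+, uc.350+ and uc.234+ were lost in 5, 5 and 4 of the 6 fits (adjusted p up to 0.136, 0.143 and 0.0843). Of 345 ultraconserved regions 25 rose and 25 fell, against 36 and 9 with the block, and of 156 nc-HOX transcripts 3 rose and 15 fell, against 11 and 3. Camera gave adjusted p = 0.291 for the ultraconserved regions and 0.0696 for the nc-HOX transcripts.

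Of the 36 members of the fixed HOX list tested in RKO, 14 rose, 2 fell and 20 did not pass. Adjusted over the list alone 15 rose and 2 fell, and the list shifted up relative to other features (median log2 fold change 0.37, camera adjusted p = 0.000189), a call lost with an estimated correlation (adjusted p = 0.205). Under the slide block 8 rose, 1 fell, the median was 0.38 and the camera adjusted p was 0.0493. PGK1 and GAPDH, the 2 glycolysis genes tested, gave camera adjusted p = 0.0473, lost with an estimated correlation (adjusted p = 0.205) and with the block (adjusted p = 0.31). PGK1 rose over all features and both rose adjusted over the list alone. None of the 3 ribosomal protein genes passed in RKO over all features or adjusted over the list alone (camera adjusted p = 0.553). COX4I1 had a log2 fold change of 0.26 (adjusted p = 0.0906). Adjusted over the list alone, which for lists with 1 tested member is the unadjusted p, COX4I1, HOTAIRM1 and EIF3D were under 0.05 and ODC1 was not. Across all features 3817 rose and 3567 fell, and 1069 and 1539 of these changed at least 2-fold. Quantile normalisation gave 3365 rises and 3763 falls and the values deposited by the authors 3435 and 3648, which turns the excess of rises. With the slide as a block, which gave the same 2459 calls among others, 3287 rose and 1848 fell, and within slide 2 alone, with 1 control array, 4162 features passed. The total of 7384 became 16561 without RKO control replicate 3, 3402 and 3240 without control replicates 1 and 2, and 3950, 3483 and 4415 without knockdown replicates 1, 2 and 3. Without control replicate 3 all controls left lay on slide 1 and all knockdown arrays on slide 2, so that fit cannot separate knockdown from slide. The RKO p-values rest on a spread shared with the HCT116 arrays. With only the 6 RKO arrays 936 features rose and 532 fell, and single features were not read from that fit.

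The direction of a HOX gene depended in places on the exon probed. The values above are from the brightest probe of each gene, and the exon numbers here are those of the probe names. For HOXB3 the exon 4 probe rose in both lines, while the exon 2 probe fell in RKO (log2 -1.09 ± 0.33, adjusted p = 0.0468) and had -0.12 in HCT116 (adjusted p = 0.977). For HOXB2 the exon 2 probe rose in RKO and the exon 1 probe fell (log2 -1.02 ± 0.22, adjusted p = 0.0122). For HOXB8 the exon 1 probe had 0.11 in RKO (adjusted p = 0.67). For HOXB5 both probes rose in RKO (log2 1.26 and 1.57), for HOXB7 both (1.00 and 0.90), and for HOXB6 3 of 4 (exons 3 and 4 by 1.24 and 1.53, and exon 1, measured on 2 of 3 control arrays, at least 2.37-fold), with exon 2 at -0.50 (adjusted p = 0.0651). For HOXC4 the exon 4 probe, chosen after its values were seen, rose in RKO (log2 0.76 ± 0.15, adjusted p = 0.00908) and in HCT116 (1.29 ± 0.15, adjusted p = 0.001), against the fall of its exon 2 probe in RKO. Taking all tested exon probes of a cluster, of 23 for HOXB 10 rose and 2 fell in RKO (median 0.46, camera p = 1.08e-05, p = 0.00125 with an estimated correlation) and 2 rose and none fell in HCT116 (median 0.34, camera p = 3.74e-06, p = 0.000919 with an estimated correlation). Of 23 for HOXA 8 rose and 1 fell in RKO (median 0.25, camera p = 0.00692, p = 0.138 with an estimated correlation) and 1 rose and 1 fell in HCT116 (camera p = 0.281). Of 18 for HOXC 7 rose and 1 fell in RKO (median 0.05, camera p = 0.0489, p = 0.0872 with an estimated correlation) and 2 and 2 in HCT116 (camera p = 0.694). Of 13 for HOXD none rose, and 1 fell in RKO and none in HCT116. These camera p-values are unadjusted, and probes of one gene count as separate members. With 1 probe per gene, the unadjusted camera p of HOXB with an estimated correlation was 0.0433 in RKO and 0.0754 in HCT116.

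Taking the HOX clusters as lists, an arrangement chosen after the data were seen, the 10 HOXB genes had a median log2 fold change of 0.60 in HCT116 and 0.88 in RKO (camera adjusted p = 0.00127 and 7.33e-05). With an estimated correlation these calls were lost (adjusted p = 0.603 and 0.346). In RKO the median with the slide as a block was 0.69, with 4 genes past the threshold and camera adjusted p = 0.0194. In HCT116 only HOXB3 of the 10 passed over all features, and 6 rose adjusted over the list alone. With the slide as a block, which changes only the spread in HCT116, 3 of them rose over all features at an unchanged median. HOXB4, HOXB8, HOXB5, HOXB6, HOXB2 and HOXB7 had log2 fold changes there of 1.16, 0.81, 0.64, 0.62, 0.57 and 0.27 (adjusted p = 0.0955, 0.0925, 0.114, 0.124, 0.0863 and 0.489), and HOXB4 0.45 in RKO (adjusted p = 0.426). The calls of HOXB4, HOXB6 and HOXB8 in HCT116 were gained without control replicate 3 (adjusted p = 0.0441, 0.0293 and 0.0246). The 11 HOXA genes shifted up in RKO (5 rose, none fell, median 0.55, camera adjusted p = 0.0137, adjusted p = 0.423 with an estimated correlation) and had a median of -0.19 in HCT116 (1 fell, camera adjusted p = 0.276). HOXC and HOXD genes as groups passed camera in neither line. The medians of the HOXB list kept their sign after quantile normalisation (0.72 in HCT116 and 0.71 in RKO).

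The difference between the responses of the 2 lines was tested directly. HOXC13 responded more positively in RKO than in HCT116 by 1.22 ± 0.19 on the log2 scale (adjusted p = 0.0102), falling in HCT116 and having a log2 fold change of 0.37 in RKO (adjusted p = 0.0841). Its exon 1 probe was well above background on 2 of 3 arrays of each RKO group, and its fitted difference of -0.24 (adjusted p = 0.765) is therefore no exact value and neither supports nor excludes the difference on exon 2. HOXA13 differed by 1.64 ± 0.27 (adjusted p = 0.0124), with -0.48 in HCT116 (adjusted p = 0.203) and a rise in RKO, and by 0.47 on its exon 1 probe (adjusted p = 0.17). Under the slide block these differences were 1.38 and 2.00 (adjusted p = 0.00811 and 0.00484), and both stayed past the threshold without any 1 of the 12 arrays. Among the ultraconserved regions, uc.341+ differed by 1.80 (adjusted p = 0.0199), and uc.12- and uc.280+ each by 1.13 (adjusted p = 0.0189). More negative in RKO were uc.456+ (-1.57, adjusted p = 0.0184), nc-HOXC11-115 (-1.24, adjusted p = 0.025) and nc-HOXA11-83 (-1.40, adjusted p = 0.0386). So were uc.196+ and uc.256+ (adjusted p = 0.0163 and 0.0387), which were well above background on no RKO knockdown array and gave no bound on the fold there. Of these, nc-HOXC11-115, nc-HOXA11-83 and uc.256+ were lost with the slide as a block (adjusted p = 0.0567, 0.0707 and 0.111), the first 2 at -0.89 ± 0.24 and -0.82 ± 0.24 against -1.24 ± 0.25 and -1.40 ± 0.32. The fitted difference of uc.256+, which is no bound, was -1.18 ± 0.39 with the block against -1.53 ± 0.35. Only HOXC13, HOXA13 and uc.196+ of the 10 kept their calls in every fit without 1 array.

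For the HOX list 5 of 36 members differed between the lines, all in the positive direction, with 10 positive and 2 negative adjusted over the list alone (median difference 0.39, camera adjusted p = 0.00255). That shift was lost with an estimated correlation (adjusted p = 0.218) and with the slide as a block (adjusted p = 0.142). The 2 glycolysis genes differed as a list (camera adjusted p = 0.0245), lost with an estimated correlation (adjusted p = 0.218) and with the block (adjusted p = 0.142), with neither gene past the threshold over all features and both adjusted over the list alone. The ribosomal protein genes did not (adjusted p = 0.266). HOTAIRM1 differed by 0.82 ± 0.19 (adjusted p = 0.0392), a call that ended with the block (0.66 ± 0.21, adjusted p = 0.0918), while ODC1, COX4I1 and EIF3D did not pass over all features. Adjusted over the list alone, again the unadjusted p, ODC1 and COX4I1 were under 0.05 and EIF3D was not. Across all features 1316 responses were more positive and 606 more negative in RKO, and 1948 and 780 with the slide as a block. The total of 1922 became 11590 without RKO control replicate 3, and 587 to 1191 without any other single array except HCT116 control replicate 1. Without that RKO control array the RKO response cannot be told apart from the slide.

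Both lines shared part of their response. HOXB3 rose in both on its exon 4 probe, while its exon 2 probe fell in RKO. Both lines called a fall of uc.234+, but no RKO knockdown array measured it and it gave no bound on the fold there. Its RKO call ended with the slide as a block (adjusted p = 0.166), where its fitted value was -1.24 ± 0.54 against -1.47 ± 0.37. Over all features 497 rose in both lines against 105 expected if the calls were independent, and 402 fell in both against 151, while 136 changed in opposite directions against 260. Among the 2895 features called in HCT116, 74.9% had the same sign in RKO and the log2 fold changes correlated with r of 0.527, whereas over all 41423 features r was 0.0617. These correlations are across features, which are not independent replicates. Under the slide block 451 rose and 613 fell in both lines. The 899 shared calls became 1606 without RKO control replicate 3, where slide and knockdown cannot be told apart in RKO. They became 468, 494 and 481 without HCT116 knockdown replicates 1, 2 and 3. They were 542 without HCT116 control replicate 2, 520 and 596 without RKO control replicates 1 and 2, and 551, 487 and 522 without RKO knockdown replicates 1, 2 and 3. The unnamed features with the largest shared changes were ASHG19A3A005312 (log2 3.76 in HCT116 and 1.91 in RKO) and ASHG19A3A020223 (3.58 and 2.09), which rose, and ASHG19A3A034682 (-2.36 and -1.54) and ASHG19A3A047038 (-2.18 and -1.58), which fell. All 4 kept their calls in RKO with the slide as a block (adjusted p = 0.00767, 0.000586, 0.000829 and 0.0169).

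Between tumour and normal samples, HOXC13 was higher in the tumour group (adjusted p = 0.0414), well above background in the 4 tumour lines and in no other sample. Its fold of 19.2 is no bound, since the tumour tissue entered the mean at its own dim signal. Its normalised log2 signal was 1.18 to 3.00 in those lines, and the tumour tissue and all normal samples were not well above background. Its second probe, on exon 1, had a difference of 0.72 (adjusted p = 0.376). The region uc.75- was at least 85.8-fold lower in the tumour group (adjusted p = 0.0197), with 3.57 ± 0.45 in the normal group, 1.98 in the tumour tissue and no tumour line well above background. On the opposite strand uc.75+ was at least 9.08-fold lower (adjusted p = 0.0246), also measured in 1 tumour sample, and uc.280+ at least 3.15-fold (adjusted p = 0.0249), measured in 4 of 5. The region uc.77-, measured in 4 normal samples and no tumour one, was lower (adjusted p = 0.0276), with a fold of 2.25 that is no bound. The region uc.452-, chosen after its values were seen, was at least 31-fold lower by group means (adjusted p = 0.0368), with 1.83 in the tumour tissue and no tumour line well above background. Its groups overlapped, as the tumour tissue did not lie below every normal sample. Without single cell lines these calls were lost for uc.75- (CCD-18Co, CCD-112CoN, CCD-841CoN or SW620, adjusted p up to 0.06), uc.75+ (CCD-33Co, CCD-112CoN, CCD-841CoN, HCT116, RKO or SW620, up to 0.0733), uc.77- (any but CCD-33Co, up to 0.0729), uc.280+ (any but RKO, up to 0.0748) and uc.452- (any line, up to 0.102).

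**Figure D3:**
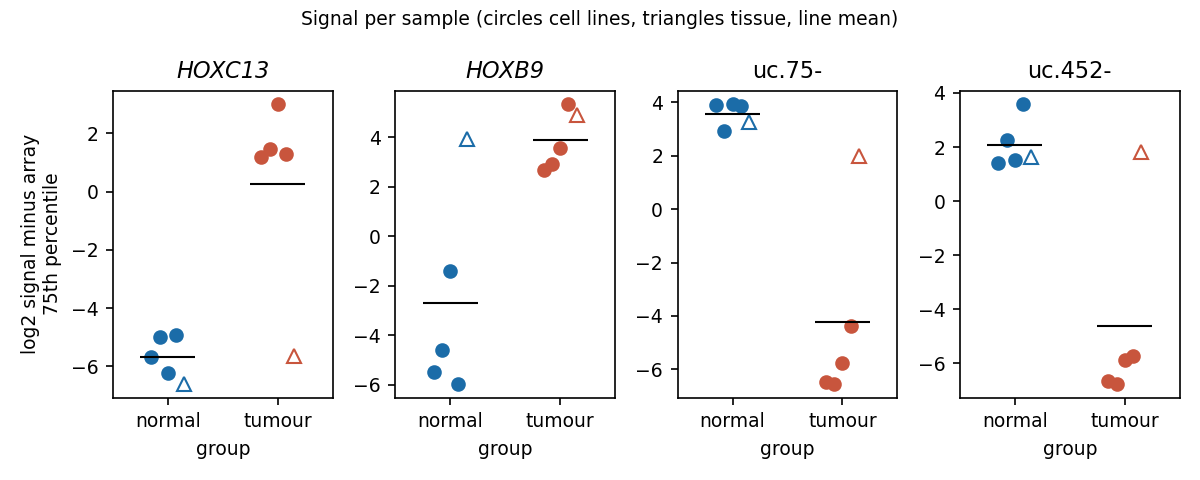
Normalised log2 signal (y axis, log2 signal minus the 75th percentile of the array) of HOXC13, HOXB9, uc.75- and uc.452- in each of 5 normal and 5 tumour samples. Circles are cell lines, triangles are tissue samples and the line is the group mean. For HOXC13, uc.75- and uc.452- the tumour tissue, at -5.64, 1.98 and 1.83, lies nearer to the normal samples than to the tumour lines, and lower points of these features are not well above background.

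Among features that were higher in the tumour group, uc.234+ had a fold of 1.5 (adjusted p = 0.0472), measured in 3 tumour samples and no normal one. The regions uc.138- and uc.58+, measured in 3 and 4 tumour samples and no normal one, had folds of 1.35 and 1.47 (adjusted p = 0.0202 and 0.0453). These folds are no bounds, since some tumour samples were not well above background. The region uc.201+, measured in 2 normal samples, was at least 2.86-fold higher (adjusted p = 0.0344). The transcript nc-HOXC6-240, chosen after its values were seen, was higher by 1.45 ± 0.30 (adjusted p = 0.0318). Of the HOX genes that did not pass, 4 were chosen after their values were seen. HOXB9, measured in 2 of 5 normal samples, and HOXB13, measured in 4 of 5, had bounds of 51.4-fold and 3.36-fold (adjusted p = 0.0569 and 0.281), and HOXB8 and HOXC10 had log2 differences of 3.02 ± 0.75 and 1.26 ± 0.31 (adjusted p = 0.0532 and 0.0508). The other exon probes of HOXB9, HOXB13, HOXB8 and HOXC10, dimmer and not measured in all samples, had positive fitted differences (adjusted p = 0.0408, 0.17, 0.348 and 0.322). Between the 4 normal and 4 tumour lines alone, HOXB9 and HOXB13 were at least 116-fold and 5.9-fold higher (adjusted p = 0.00141 and 0.00442), and HOXB8 and HOXC10 were higher by 3.21 and 1.36 (adjusted p = 0.0396 and 0.0208). HOXC13 was at least 49.5-fold higher there and uc.75- at least 209-fold lower (adjusted p = 5.61e-05 and 1.67e-05), each measured in all 4 lines of one group and none of the other. As lists chosen after the data were seen, the HOXA, HOXB, HOXC and HOXD genes had median fitted differences of 1.52, 0.55, 0.99 and -1.05, and camera passed for none (adjusted p = 0.0593, 0.18, 0.0593 and 0.193). With the slide as a block the medians were 0.82, 0.14, 1.58 and -2.69 (adjusted p = 0.599, 0.911, 0.258 and 0.112). After quantile normalisation the HOXD median was -0.25, with another probe of HOXD11 as the brightest, and -1.10 with the probes unchanged. Of 308 ultraconserved regions 6 were higher and 5 lower, and of 150 nc-HOX transcripts 1 was higher. Without single cell lines the calls were lost for uc.234+ (any line, adjusted p up to 0.112), uc.58+ (any line, up to 0.109, and the tumour tissue, 0.0522), uc.201+ (any but CCD-18Co, up to 0.0929), nc-HOXC6-240 (any but CCD-33Co, up to 0.0895) and uc.138- (CCD-18Co, CCD-112CoN, CCD-841CoN or SW620, up to 0.0655). Without the normal tissue HOXB9, HOXB8, HOXC10 and HOXB13 passed (adjusted p = 0.000986, 0.0296, 0.0173 and 0.00321), as did HOXB8 without CCD-841CoN or RKO (0.0483 and 0.0461) and HOXC10 without HT29 (0.0473). Without any 1 of the normal lines the exon 2 probe of HOXB13 became the brightest in place of exon 1, with fitted differences of 4.16 to 4.46 (adjusted p = 0.287 to 0.33). On those arrays exon 1 gave 1.40 to 1.58, and in the other fits without 1 sample 1.51 to 2.64. Within slide 3, where the normal tissue is the only normal sample, HOXB13 had fitted differences of -1.82 on exon 1 and -3.34 on exon 2. The sign of HOXB13 was thus turned against that tissue.

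Of the 35 members of the fixed HOX list tested between tumour and normal samples, 1 was higher, 4 were higher adjusted over the list alone and none was lower (median difference 0.58, camera adjusted p = 0.0586). Between the cell lines alone, where other probes of HOXD11 and HOXD13 were the brightest, camera gave adjusted p = 0.038 (0.085 with an estimated correlation), and adjusted p = 0.0636 with the probes unchanged. No ribosomal protein or glycolysis gene and none of ODC1, EIF3D, COX4I1 and HOTAIRM1 passed over all features or adjusted over the list alone (camera adjusted p = 0.604 for both lists). Across 39911 features, whose median difference was 0.14, 629 were higher and 839 lower in the tumour group, and each named change was larger than that median. With 4 lines and 1 tissue per group, the calls mainly compare the lines, whose cell types were not analysed. All normal lines lay on slide 2 and all tumour samples on slide 3. With the slide as a block, in which the normal tissue is the only normal sample beside the tumour samples, 157 were higher and 106 lower, and 40 of the 1468 calls remained, no named feature among them. The fitted values of HOXC13 and uc.75-, which are no bounds, were 6.86 ± 2.45 and -7.50 ± 2.58 with the block (adjusted p = 0.199 and 0.186), against 5.95 ± 1.35 and -7.82 ± 1.41. Within slide 3, with 1 normal sample, limma called 0 features, and 4639 had an unadjusted p under 0.05. The 1468 calls became 4975 without the normal tissue, 2630 without the tumour tissue and 346 to 658 without any 1 of the 8 cell lines, and HOXC13 lost its call without any 1 of those lines (adjusted p up to 0.0974).

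The knockdown and tumour comparisons share no array, but the tumour group holds untreated HCT116 and RKO, and slide 2 carried all RKO knockdown arrays and the 4 normal lines. The counts expected from independent lists take no account of either. Of the 394 features that fell in both knockdown lines and were tested between tumour and normal samples, 42 were higher in the tumour group against 6.33 expected, and 1 was lower against 5.86. Their median difference was 0.95, and camera placed them above the other features (p = 2.89e-17, p = 0.0156 with an estimated correlation). The only named one of the 42 was uc.234+, whose fall in RKO gave no bound on the fold. Of the 488 features that rose in both lines, 24 were lower in the tumour group against 7.26 expected and 5 were higher against 7.84 (camera p = 1.38e-08, p = 0.00294 with an estimated correlation). The 42 became 9 with the slide as a block, against 2.43 expected and with 1 of the 42 among them, 79 without the normal tissue, 86 without the tumour tissue and 12 to 20 without any 1 of the 8 cell lines. Without RKO knockdown replicate 3 or 2, RKO control replicate 1 or HCT116 knockdown replicate 1 they became 21, 25, 27 and 27. With untreated HCT116 and RKO left out of the tumour group, a test chosen after the data were seen, 4 of the 42 remained, with no others, against 1.14 expected. For all features that fell in HCT116, whose arrays lay on slide 1, that tumour contrast gave 14 against 4.93 expected, 4 of them among the 42.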

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

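Tests chosen only after the results were seen were that of the RKO falls against the control array of the same slide, those of unspliced RNA and of the slide for the HOXB rise, and the choice of uc.452-, HOXB13, HOXC10 and DYNLL1 as features of the text.

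In 5 of 30 groups of 5 normal or tumour samples, over 15 named features, 1 sample lay far from the others, where chance gives about 1 in 20 groups. Signals not well above background are among these values, and they set part of the range. The gap to the nearest sample, as a share of the range of the group, was 0.789 for HOXC13, 0.748 for uc.75- and 0.878 for uc.452- in the tumour group, each with the tumour tissue apart from the 4 lines. It was 0.854 for HOXB13 and 0.829 for uc.280+ in the normal group, against a critical value of 0.71.

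Of all 609 named features, 16 responded more positively and 8 more negatively in RKO than in HCT116, and 4.64% of all features differed. Among the features of the text, the response to MYC knockdown differed between the lines for 16. Those with the 5 smallest adjusted p of this difference in each direction were in the text for that reason, so this count is partly fixed by the choice. The differences, RKO minus HCT116 on the log2 scale, were 1.64 for HOXA13, 1.27 for HOXC10, 1.22 for HOXC13, 1.04 for HOXA10, 0.83 for DYNLL1 and 0.82 for HOTAIRM1. They were 1.80 for uc.341+, 1.13 for uc.12-, 1.13 for uc.280+ and 0.90 for uc.416-, and -1.40 for nc-HOXA11-83, -1.24 for nc-HOXC11-115, -1.74 for uc.196+, -1.53 for uc.256+, -1.57 for uc.456+ and -2.17 for uc.458+. Those of uc.196+, uc.256+ and uc.458+ are fitted values and no bounds, since no RKO knockdown array was well above background for them. With the slide as a block the difference was 0.59 ± 0.15 for DYNLL1 (adjusted p = 0.0522), 0.66 ± 0.21 for HOTAIRM1 (0.0918), 0.91 ± 0.28 for HOXA10 (0.0848), 1.19 ± 0.37 for HOXC10 (0.088), 0.71 ± 0.23 for uc.416- (0.0959) and -1.17 ± 0.39 for uc.458+ (0.108), with standard errors of 0.18, 0.19, 0.24, 0.30, 0.21 and 0.54 without the block. The exon 1 probes of HOXA10 and HOXC10 gave -0.37 and -0.24 (adjusted p = 0.339 and 0.479).

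The HOXB rise after MYC knockdown had a median log2 fold change of 0.88 over 10 genes in RKO. As for a brightness trend, none of 10000 lists of equally bright features had a median as high in either line, which argues against it. The share of 0.01% in each line is the HOXB list itself, counted among them. As for unspliced RNA or DNA, the median of 44 HOXB introns and nc-HOXB transcripts in RKO was -0.18 (quartiles -0.41 and 0.30), below the 0.88 of the exons. That value is without the slide block. In HCT116, whose arrays shared 1 slide, the median was 0.00438 against 0.60 for the exons. This argues against a rise of these probes as a set along with the exons. Introns were not tested apart from the nc-HOXB transcripts, so unspliced HOXB RNA alone stays open. The slide is argued against as the whole cause by the median of 0.60 in HCT116, whose arrays shared 1 slide. It also stays open why exon 1 of HOXB2 and exon 2 of HOXB3 fell in RKO, and an effect of the knockdown itself was not tested, since the level of MYC was not read.

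The 1539 falls of at least 2-fold in RKO had a median of -1.38. Over them, RKO control replicate 3 minus untreated RKO on slide 3 had a median of -0.27 (-0.15 over all features), control replicates 1 and 2 minus untreated RKO 0.50 and the knockdown arrays -1.12. Against the control array of the same slide the median was -0.87 and 100% were negative, with 406 falls past the threshold, and for the 1069 rises 0.92 (1.39 without the block) with 552 past it. The slide and the knockdown cannot be told apart as shares of the falls, since 1 control array lay on the slide of the knockdown arrays. Both may contribute.

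The tumour and normal samples lay on different slides. Over the 658 features called without the untreated RKO array (median size 3.38), untreated RKO on slide 3 minus RKO control replicate 3 on slide 2, signed by the call, had a median of 0.27, and minus the 3 knockdown arrays 0.34, 0.41 and 0.39, which argues against the slide as the whole cause. Of the 6825 features called between the lines (median size 1.95), 51.2% had the same sign between the tissues (60.2% of those higher and 43.4% of those lower in the tumour lines, with 62.9% of all features higher in the tumour tissue) and the median signed tissue difference was 0.06. The normal lines correlated with each other at r of 0.945 to 0.964 and with the normal tissue, on another slide, at 0.836 to 0.847. The tissues correlated with each other at 0.904, more than either did with any line. These values go with a difference between kinds of cell line rather than tumour state. CCD-18Co is a fibroblast line, and the types of the other lines were not analysed. With 1 tissue per side, tumour state stays open as an explanation.

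Other splits of the same samples were counted over features without missing spots. In HCT116 the 10 splits are too few for a share under 0.05 (2885 calls in the real split, highest other 1), as in RKO (7360, highest other 156, from a split that puts RKO control replicate 3 with 2 knockdown arrays). They are too few as well for the HOX list in RKO, where under this permutation of the arrays limma's camera gave p = 6.22e-05 in the real split and 0.0038 as the smallest of the others. Of 100 splits, 1, the real one, gave as many calls for the difference between lines (1909, highest other 696) and for both lines (898, highest other 4). The same held for tumour and normal samples (1464, highest other 1140) and for the overlap (42, highest other 10). This argues against a random grouping of the arrays as the source of these counts. The real split also parts the RKO arrays and the normal and tumour samples largely by slide. These counts therefore cannot separate the groups from the slide. For the overlap only the normal and tumour arrays were split, with the knockdown features unchanged. The split with 1140 calls put both tissues with 3 of the tumour lines, which points to a structure of the samples.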

How the results depend on the processing

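The normexp correction on the median signal, the fits on single slides, the slide as a block for the lists and for single features, the overlap without untreated HCT116 and RKO, the lists with unchanged probes, and the probe families were chosen after the data were seen. The planned normexp correction on the mean signal was not run, since the files lack that value. Signal over background limits the dim features: the RKO control array of slide 2 minus those of slide 1 had a median of -0.64 in the dimmest of 5 equal classes of features and 0.25 in the brightest.

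Counts stayed within 1.5 times the reported one except as follows, and the cause was not tested unless fewer samples or features show it. In HCT116 2895 calls became 1700 with no filter on dim probes, 4970 with the slide as a block, 589 with the replicate number as a block, 676 at 2-fold and 1389 to 2257 without 1 array. The slide block leaves the HCT116 fold changes as they are, since those arrays shared 1 slide, and changes only the spread. In RKO 7384 became 4410 with no filter, 2835 with the replicate block, 2608 at 2-fold, 1468 with only the 6 arrays of the line, 4162 within slide 2 and 3240 to 16561 without 1 array. The difference (1922) became 612 with no filter, 2927 with every array above background, 2 with the replicate block, 1176 at 2-fold and 587 to 11590 without 1 array. Tumour calls (1468) became 830 with no filter, 510 with every array above background, 263 with the slide block, 6825 between cell lines only, 7934 with array weights, 0 within slide 3 (limma; 4639 at an unadjusted p under 0.05) and 346 to 4975 without 1 array. The calls shared by both lines (899) became 591 with a median shift, 439 with no filter, 153 with the replicate block, 82 at 2-fold and 468 to 1606 without 1 array. The highest RKO, difference and shared counts came without RKO control replicate 3, where the slide and the knockdown cannot be told apart. The overlap (42) became 25 with a median shift, 14 with no filter, 9 with the slide block, 132 between lines only, 146 with array weights, 0 within slide 3, 5 at 2-fold, 11 with the replicate block, 12 to 86 without 1 array, 4 with untreated HCT116 and RKO left out of the tumour group and 14 for the falls of HCT116 alone in that contrast. Of the 4 list shifts past the threshold 1 was left with the slide block and 0 with an estimated correlation. Replicate numbers did not pair the arrays (correlations of -0.23 to 0.17 between equal numbers in HCT116).

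The share of calls that rose went from 39.4% to 50.8% in HCT116 and from 68.5% to 54.5% for the difference after quantile normalisation, and from 51.7% to 64.2% in RKO with normexp. The reference mRNAs in HCT116 had a median of 0.00819 after quantile normalisation against -0.21. Other probes of a gene turned the sign for HOXB3 in HCT116 (-0.19 and -0.12) and RKO (-1.09), HOXB6 (-0.50), HOXB2 (-1.02), HOXA10 (-0.31) and HOXC4 (0.76) in RKO, and HOXC13 for the difference (-0.24, fitted on arrays partly not well above background); the cause was not tested. For named features, fits without 1 array kept 359 calls or non-calls, lost 175 and gained 12, with 0 reversed, and the other settings kept 338, lost 106, gained 24 and reversed 8. For lists they kept 192, lost 21, gained 6 and reversed 1.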

Other observations

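The reference mRNAs of the array, chosen as a list after the data were seen, had a median log2 fold change of -0.21 in HCT116 (20 tested, 1 fell, camera adjusted p = 0.00156, adjusted p = 0.765 with an estimated correlation) and 0.18 in RKO (3 rose, 1 fell, adjusted p = 0.0418, adjusted p = 0.719 with an estimated correlation). With the slide as a block the RKO median was 0.04 (adjusted p = 0.975), and after quantile normalisation the HCT116 median was 0.00819. Introns of the HOX regions had 1 rise and 1 fall among 29 tested in HCT116 and 2 and 2 in RKO, where the slide as a block gave 5 and 0. The exon 3 probe of HOXB6 rose in HCT116 (log2 0.65, adjusted p = 0.00861).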
